A study of Escherichia coli with 64 samples.

How the data were processed

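Gene expression was measured on 64 Agilent 2-colour arrays of 8 slides, with 8 arrays each, scanned on 6 days. Per the labels' protocols, RNA was stabilised in phenol and ethanol, purified on columns, and labelled with Cy3 or Cy5 during reverse transcription. Groups, dyes and replicate numbers were taken from the labels alone. The labels tell biological experiments apart, and p-values measure the spread between them, pooled over the groups.

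Per the file headers, the deposited scanner files hold raw median intensities of spot and local background for each of 15744 spots and dye. Per the headers they also hold background-subtracted, dye-normalised processed intensities and the log10 ratio of Cy5 over Cy3 of these. Per the submitters' processing notes, Agilent Feature Extraction 10.10.1.1 produced them, and the genome build behind the array's design is not given in the sources used here. The deposited values of the authors hold that log10 ratio with the sign of the swapped arrays turned to test over reference and no further centring, as setting each of its columns against the scanner values showed, and column medians lay between 0 and 0.0571, with 5 arrays off 0. A scanner file that had been saved again by a spreadsheet was read with its quotes stripped.

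From the median intensities, log2 ratios were computed here with limma 3.58.1 and the package data.table (1.17.8) in R 4.3.3. The plan had named mean signals, but the files carry medians, which were used instead. Background was corrected by normexp with an offset of 50 on all spots, and each array was normalised by loess with its 556 control spots at weight 0. The offset draws ratios of dim spots towards 0. Spots marked as outliers by the scanner software were left out, between 4.23 and 6.36% of an array's non-control spots, and saturated spots were kept. Spots of a probe were averaged, then probes of a gene, each array was turned to test over reference, and dye swaps were averaged to 1 value per culture and time, which cancels a dye effect common to both where both are used. A probe was kept when it was well above background on at least 4 of the 64 arrays in either channel. Of 4538 named probes 4150 were kept, for 4079 genes, and 1064 probes were above background on all arrays. Of 4598 non-control probes, 4235 carry a b-number, with 4053 of the 4210 b-numbers found in the reference table of assembly ASM584v2, which was used for names alone, and 303 are named by symbol, with 242 found. The other 60 have no gene name and were left out. Median green signals lay between 54 and 261.75 and median red ones between 91 and 318, and the dimmest arrays were those of WT with CORM-3.

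For each culture the 5 times were averaged, since they share a reference. The 6 culture means and the 2 values before addition entered 1 limma fit (lmFit, eBayes) of 4 groups, with 4 residual and 1.98 prior degrees of freedom. Tests were the 4 coefficients against 0 and the differences of hemA with CORM-3 from WT with CORM-3 and from hemA with iCORM-3, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over genes. The same fit was repeated at each of the 5 times, for 25 comparisons. A set of 35 gene lists from textbook regulons and pathways, with 644 members of which 618 were measured, was tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over 210 tests of 6 comparisons, with an estimated correlation as an alternative. Limma's fry, which asks whether a set moves and does not compare it with other genes, was run beside it. A gene not well above background in any array of a series on 1 side, test or reference, was given as at least N-fold. The mean signal of the other side was set against a dim side raised, on each array, to at least the lowest signal well above background, with channels scaled by limma's Aquantile. The rule for naming genes was fixed before the data were examined, as were the lists, the tests and the alternatives not said to be chosen later. The rule took the 8 highest and 8 lowest log2 values past the test with the same sign in both cultures (for differences, both cultures of a series above both of the other), the 3 largest members past the test of each list called, and a fixed set of genes whatever their values. For length not every gene the rule picked is printed, and cyoA and metF were below the filter. List members not well above background, among them genes of flagella and sulphonate uptake, are not analysed here.

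The fit was tested on simulated data for the mean response of hemA to CORM-3 alone, with 4000 genes of which 200 changed, over 20 runs. It called 21.6% of genes changed by a log2 of 0.5, 86.2% at 1, 99.1% at 2 and 100% at 4, with a mean of 8.2 unchanged genes called per run. The simulated spread was not set against these groups (SD of culture differences 0.216 to 0.537), so rates here may differ. Alternatives covered the background correction, normalisation, processed intensities, authors' values, filter, summary of probes, a log2 threshold of 1, a single dye orientation, an intensity trend, blocks for culture, replicate number and slide, a dye term for each slide, and each replicate left out. After the data had been seen, further fits were added, as named with their counts below.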

Results

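Transcript levels were measured in Escherichia coli K-12 MG1655, the wild type (WT), and in a derivative labelled hemA. The hemA gene encodes glutamyl-tRNA reductase, which starts the synthesis of haem, the cofactor of cytochromes. Batch cultures grown without air in a defined medium received 100 µM CORM-3, a ruthenium carbonyl that releases carbon monoxide, or 100 µM iCORM-3, its inactive form per the labels. RNA taken 10, 20, 40, 60 and 120 min later was hybridised on 2-colour Agilent arrays against RNA from the time of addition. Each of the 3 time courses (WT with CORM-3, hemA with CORM-3, hemA with iCORM-3) had 20 arrays, with 2 biological experiments and both dye orientations, and 4 more arrays set hemA against WT before addition. No untreated culture followed over time was analysed here, so each response is a change against the start that includes the time in culture.

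Across the arrays, between 32.1 and 81.2% of probes were well above background in the treated WT samples, 46.8 and 79.8% in hemA with CORM-3, 54.6 and 88.3% in hemA with iCORM-3, and 71.5 and 79.4% in hemA before addition. Values are log2 ratios, averaged over the 5 times for the responses, ± the standard error (SE) of the limma fit with n = 2 cultures per group, and the number of arrays and cultures limits their precision. Dye-swap pairs of the same RNA off slide 16 correlated across genes at r between 0.87 and 0.98. Slide 16 carried 8 of the 20 arrays of hemA with CORM-3, and pairs with an array on it lay between -0.89 and 0.92. Its 120 min arrays, 2 in number, correlated with the other 120 min arrays at -0.98 to -0.88, while those 2 others correlated with each other at 0.85 and with a 60 min array at 0.96 and 0.79. These arrays of slide 16 thus ran opposite to their series, for a reason not settled. Mean responses of hemA with CORM-3 are therefore given over all arrays and again without slide 16, a setting chosen after the data were seen, and total counts also with the sign of those arrays turned. Without slide 16, replicate 2 has no 10 min value and its test RNA in Cy3 only, and replicate 1 has Cy5 only at 60 and 120 min, so dye effects do not cancel there and the cultures cover different times.

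**Figure D1:**
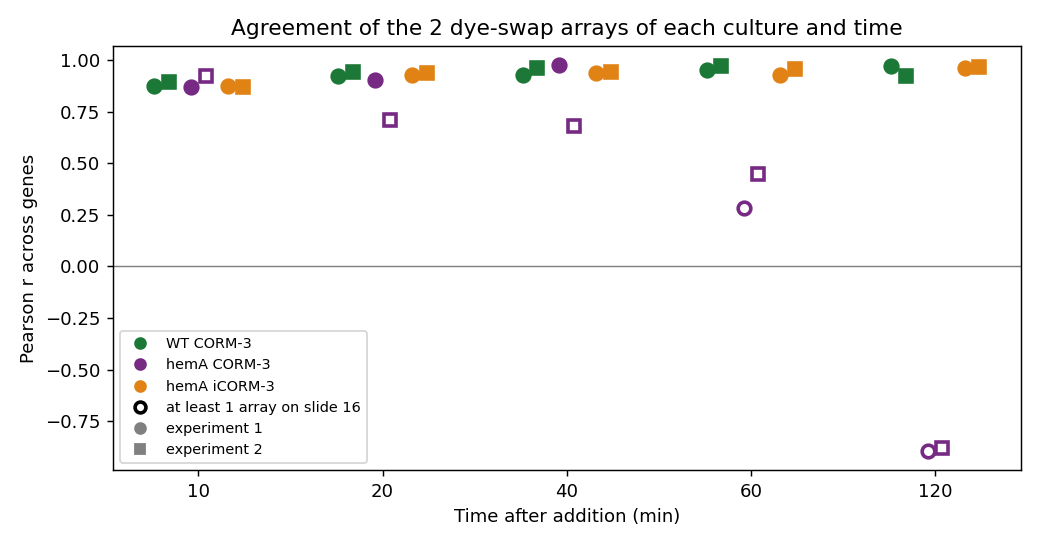
Pearson r across genes (vertical axis) between the dye-swap arrays of each culture, against time after addition in minutes (horizontal axis), filled off slide 16 and open with an array on it. Pairs of hemA with CORM-3 on slide 16 range down to -0.89.

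The arrays before addition asked how the strains differed at the start. The hemA gene itself, seen by 1 probe, was higher in the cultures labelled hemA by 1.37 ± 0.067 (adjusted p = 0.000199), with 1.34 and 1.40 in the 2 experiments. The sources do not say if that probe lies in the altered part of the gene, so it does not settle the strain label, and directions are for cultures labelled hemA. Over the time courses the same gene read -0.080 and 0.12 in WT with CORM-3, -0.11 and -0.11 in hemA with CORM-3, and 0.45 and 0.41 in hemA with iCORM-3, each against its own start. At the start, cultures labelled hemA had more transcript of nitrate and nitrite respiration and of cytochrome bd oxidase, and less of asparagine synthesis and formate hydrogenlyase. The highest gene was narK (b1223), a nitrate and nitrite transporter, at 4.47 ± 0.29 (adjusted p = 0.000458), which is 22.1-fold. It was followed by nirB (b3365) of the NADH-dependent nitrite reductase at 4.14 ± 0.23 (adjusted p = 0.000268), whose partner nirD stood at 3.65. The lowest were asnA (b3744), asparagine synthetase A, at -5.59 ± 0.42 (adjusted p = 0.000783), and yjiH at -4.87 ± 0.15. In all, 603 genes were higher and 510 lower among 4079 tested, 118 and 101 of them by at least 2-fold.

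In anaerobic respiration, 23 of 39 members were higher, 7 were lower and 9 did not pass (23 higher and 7 lower adjusted over the list alone). Its median was 1.40 (camera adjusted p = 5.64e-06, adjusted p = 0.511 with an estimated correlation). Among its higher members were fdnG, formate dehydrogenase-N, at 3.35 ± 0.14 (adjusted p = 0.000148) and napH of the periplasmic nitrate reductase at 3.27 ± 0.15. Of the terminal oxidases, 5 of 11 members were higher and 6 did not pass (6 higher and 1 lower adjusted over the list alone), with the cytochrome bd-I genes cydX at 3.41 ± 0.15, cydB at 3.23 ± 0.11 and cydA at 3.13 ± 0.077 (adjusted p = 6.26e-05), and appC of bd-II at 0.98 ± 0.28 (adjusted p = 0.049). The list's median was 0.40 (camera adjusted p = 0.00845, adjusted p = 0.462 with an estimated correlation). In the ribonucleotide reductases, 6 of 9 members were higher and 3 did not pass (7 adjusted over the list alone). A median of 1.00 resulted (camera adjusted p = 0.00467, adjusted p = 0.581 with an estimated correlation). Members included nrdA at 2.28 ± 0.40 (adjusted p = 0.0112). In purine biosynthesis, 7 of 15 members were higher and 8 did not pass (9 adjusted over the list alone). The median was 0.75 (camera adjusted p = 7.7e-05, adjusted p = 0.511 with an estimated correlation). Highest were purA at 2.16 ± 0.24 (adjusted p = 0.00284) and purT at 1.94. In the RpoS general stress list, 12 of 18 members were higher and 6 did not pass (14 adjusted over the list alone). Its median was 0.71 (camera adjusted p = 5.28e-06, adjusted p = 0.366 with an estimated correlation). Members included osmB, a lipoprotein gene induced by osmotic stress, at 2.13 ± 0.32 (adjusted p = 0.00687) and katE, catalase HPII, at 1.47. Other genes among the highest were cadA, lysine decarboxylase, at 3.87 ± 0.51 (adjusted p = 0.00473) and grcA, which replaces the damaged radical domain of pyruvate formate-lyase, at 3.79 ± 0.22.

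In the fermentation and hydrogenase list, 6 of 28 members were higher, 15 were lower and 7 did not pass (8 higher and 15 lower adjusted over the list alone). A median of -0.86 resulted (camera adjusted p = 0.0398, adjusted p = 0.908 with an estimated correlation). The lowest were fdhF, formate dehydrogenase-H, at -2.68 ± 0.15 (adjusted p = 0.000268) and hycE at -2.53, while adhE, the alcohol dehydrogenase of mixed-acid fermentation, was higher at 0.97 ± 0.23 (adjusted p = 0.0274). In pyrimidine biosynthesis, 5 of 11 members were lower and 6 did not pass (5 adjusted over the list alone). The median was -1.06 (camera adjusted p = 0.00179, adjusted p = 0.574 with an estimated correlation). The lowest of these, carA at -3.90 ± 0.33 (adjusted p = 0.00112) and carB at -3.36, encode carbamoyl phosphate synthetase and also stand in the arginine list, where 4 of 12 members were lower and 8 did not pass (4 adjusted over the list alone). Its median was -0.29 (camera adjusted p = 0.00368, adjusted p = 0.366 with an estimated correlation). In ATP synthase, 8 of 9 members were lower and 1 did not pass (9 adjusted over the list alone). A median of -0.84 resulted (camera adjusted p = 0.000168, adjusted p = 0.581 with an estimated correlation). In the sugar uptake list, 6 of 26 members were lower and 20 did not pass (5 adjusted over the list alone). The median was -0.56 (camera adjusted p = 0.000451, adjusted p = 0.795 with an estimated correlation). In the metal list, 7 of 30 members were lower and 23 did not pass (7 adjusted over the list alone). Its median was -0.16 (camera adjusted p = 0.0222, adjusted p = 0.594 with an estimated correlation). Further genes among the lowest were asnB, asparagine synthetase B, at -4.12 ± 1.04 (adjusted p = 0.034) and ansB, asparaginase II, at -2.61 ± 0.39. In NADH dehydrogenase I, 7 of 13 members were higher and 6 did not pass (8 adjusted over the list alone). A median of 0.50 resulted (camera adjusted p = 0.000861, adjusted p = 0.581 with an estimated correlation). In the phage shock list, 5 of 7 members were higher and 2 did not pass (5 adjusted over the list alone). The median was 0.62 (camera adjusted p = 0.00514, adjusted p = 0.511 with an estimated correlation). In the sigma E envelope stress list, 4 of 20 members were higher, 1 was lower and 15 did not pass (4 higher and 1 lower adjusted over the list alone). Its median was 0.32 (camera adjusted p = 0.0291, adjusted p = 0.795 with an estimated correlation). In histidine biosynthesis, 3 of 8 members were higher and 5 did not pass (5 adjusted over the list alone). A median of 0.56 resulted (camera adjusted p = 0.0235, adjusted p = 0.791 with an estimated correlation). Fry did not call the sigma E, histidine and sugar uptake lists (adjusted p from 0.0732 to 0.132). In single-channel start signals, a check chosen after the data were seen and not tested, the median of hemA against WT in the CORM-3 and iCORM-3 sets was 1.27 and -0.96 for purine, -1.48 and 2.18 for pyrimidine, -0.56 and 0.0077 for arginine and 0.74 and -0.074 for ribonucleotide reductase genes, so these list differences were not shared by both sets. The other lists called kept their direction, with NADH dehydrogenase I at 0.84 and 0.18 and histidine at 0.34 and 0.035. Of genes named whatever their values, katG, catalase HPI, was lower at -0.92 ± 0.11 (adjusted p = 0.00321), hmp, the nitric oxide dioxygenase, was higher at 0.86 ± 0.089 (adjusted p = 0.00213), and hemL, the next enzyme of haem synthesis, read 0.0088 ± 0.21 (adjusted p = 0.979). Centring each array on its median in place of loess moved the typical gene by 0.18, and 70.8% of calls were then higher against 54.2%.

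The WT time course asked how cells with haem responded to CORM-3. The response was led by genes of envelope stress: spy (b1743), a periplasmic chaperone, rose by 9.71 ± 0.13 (adjusted p = 1.73e-06), or 837-fold. The gene cpxP (b4484), which encodes the inhibitor of the CpxA sensor, rose by 5.73 ± 0.21 (adjusted p = 7.53e-05), and the efflux gene mdtA, not well above background at the start, rose at least 27.2-fold (adjusted p = 5.69e-05). Members of the heat shock and iron uptake lists rose with them, and members of the ribosomal protein, ATP synthase, NADH dehydrogenase and purine lists fell. Over all genes, 646 rose and 558 fell, 188 and 171 of them by at least 2-fold.

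In the Cpx and Bae list, 16 of 18 members rose and 2 did not pass (17 adjusted over the list alone). The median was 1.70 (camera adjusted p = 4.99e-11, adjusted p = 0.366 with an estimated correlation). Features named only b3914 and b3913, not listed in the reference table, rose by 6.04 ± 0.26 and 5.76 ± 0.25, and yebE, an inner membrane protein gene, by 4.22 ± 0.13 (adjusted p = 5.69e-05). In the heat shock list, 15 of 20 members rose and 5 did not pass (18 adjusted over the list alone). Its median was 1.33 (camera adjusted p = 1.84e-07, adjusted p = 0.581 with an estimated correlation). Members included the small chaperones ibpB at 3.90 ± 0.42 (adjusted p = 0.00192) and ibpA at 2.73, the membrane protease htpX at 3.41 ± 0.17 and dnaK at 2.18 ± 0.23 (adjusted p = 0.00192). Of the iron acquisition genes, 26 of 36 members rose and 10 did not pass (29 adjusted over the list alone). A median of 0.77 resulted (camera adjusted p = 3.8e-08, adjusted p = 0.511 with an estimated correlation). Among them were feoA of ferrous iron uptake at 2.31 ± 0.40 (adjusted p = 0.0103), fhuF, a ferric siderophore reductase, at 2.15, entC of enterobactin synthesis at 1.98 and its receptor fepA at 1.51. In the phage shock list, 4 of 7 members rose and 3 did not pass (7 adjusted over the list alone). The median was 0.62 (camera adjusted p = 0.000954, adjusted p = 0.462 with an estimated correlation). Highest was pspA at 1.15 ± 0.083 (adjusted p = 0.000497). In the RpoS list, 10 of 18 members rose, 1 fell and 7 did not pass (11 up and 1 down adjusted over the list alone). Its median was 0.67 (camera adjusted p = 0.00287, adjusted p = 0.412 with an estimated correlation). In aromatic amino acid biosynthesis, 4 of 13 members rose, 1 fell and 8 did not pass (5 up and 1 down adjusted over the list alone). A median of 0.23 resulted (camera adjusted p = 0.0291, adjusted p = 0.581 with an estimated correlation). In the SOS list, 6 of 22 members rose and 16 did not pass (6 adjusted over the list alone), and its median of 0.31 turned to -0.054 under median centring (camera adjusted p = 0.0222, adjusted p = 0.878 with an estimated correlation). The ribosome hibernation factor raiA rose by 4.63 ± 0.50 (adjusted p = 0.00192), the biofilm regulator bssS by 3.91 ± 0.37 and lactate dehydrogenase ldhA by 2.09 ± 0.25 (adjusted p = 0.00274).

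Of the ribosomal protein genes, 44 of 52 members fell and 8 did not pass (44 adjusted over the list alone). The median was -1.57 (camera adjusted p = 3.9e-25, adjusted p = 0.366 with an estimated correlation). In purine biosynthesis, 8 of 15 members fell and 7 did not pass (11 adjusted over the list alone). Its median was -0.97 (camera adjusted p = 9.09e-06, adjusted p = 0.475 with an estimated correlation). The GMP branch genes guaB (b2508) and guaA fell most, at -3.12 ± 0.42 and -2.95 ± 0.40 (adjusted p = 0.00417). In pyrimidine biosynthesis, 2 of 11 members fell and 9 did not pass (5 adjusted over the list alone). A median of -0.81 resulted (camera adjusted p = 0.0095, adjusted p = 0.606 with an estimated correlation). In NADH dehydrogenase I, 10 of 13 members fell and 3 did not pass (11 adjusted over the list alone). The median was -0.63 (camera adjusted p = 4.31e-06, adjusted p = 0.511 with an estimated correlation). In ATP synthase, 7 of 9 members fell and 2 did not pass (8 adjusted over the list alone). Its median was -1.16 (camera adjusted p = 0.000392, adjusted p = 0.581 with an estimated correlation). In the fermentation and hydrogenase list, 1 of 28 members rose, 11 fell and 16 did not pass (1 up and 12 down adjusted over the list alone). A median of -0.39 resulted (camera adjusted p = 0.002, adjusted p = 0.795 with an estimated correlation). In the acid resistance list, 5 of 14 members fell and 9 did not pass (6 adjusted over the list alone). The median was -0.61 (camera adjusted p = 0.0013, adjusted p = 0.515 with an estimated correlation). In haem biosynthesis, 1 of 13 members rose, 7 fell and 5 did not pass (1 up and 7 down adjusted over the list alone). Its median was -0.49 (camera adjusted p = 0.00448, adjusted p = 0.565 with an estimated correlation). In anaerobic respiration, 1 of 39 members rose, 13 fell and 25 did not pass (1 up and 13 down adjusted over the list alone), with frdA of fumarate reductase at -1.73 ± 0.34 (adjusted p = 0.0143) and hydrogenase 2 genes hybA at -1.34 and hybB at -1.33, and its median of -0.091 turned to 0.050 with the scan day as a random block (camera adjusted p = 0.0428, adjusted p = 0.795 with an estimated correlation). The anaerobic ribonucleotide reductase nrdD fell, at -2.70 ± 0.55 (adjusted p = 0.0157), the porin ompF at -2.62 ± 0.091, the sulphite reductase gene cysJ at -2.35 ± 0.47 (adjusted p = 0.0157) and cydA at -1.26 ± 0.077 (adjusted p = 0.000263). The hmp gene read -0.016 ± 0.089 (adjusted p = 0.909), norV, the anaerobic nitric oxide reductase, -0.072 and nirB 0.021, none past the test. Median centring moved the typical gene by -0.15 and left 27.1% of calls higher against 53.7%. Fry did not call the anaerobic respiration, fermentation, SOS and pyrimidine lists (adjusted p from 0.0732 to 0.132). Without replicate 1 of this series 472 genes passed.

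The hemA cultures with CORM-3 asked how cells lacking haem, per the strain label, responded to the same dose. Here too spy rose most, by 7.28 ± 0.13 (adjusted p = 9.66e-06), or 9.17 without slide 16, with mdtA at 4.22 ± 0.15 (adjusted p = 0.000181), or 5.18 without slide 16, and cpxP at 3.52 ± 0.21 (adjusted p = 0.000635), or 4.63 without slide 16. Members of the iron acquisition and sulphur lists and hmp rose, while lysine decarboxylase and some genes of nitrate respiration and purine synthesis fell. Over all arrays 323 genes rose and 317 fell, against 610 and 654 without slide 16, and the total went from 640 to 1401 with the sign of the doubtful 120 min arrays turned. By at least 2-fold, 135 rose and 69 fell, or 228 and 225 without slide 16.

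In the Cpx and Bae list, 16 of 18 members rose and 2 did not pass (18 adjusted over the list alone). A median of 1.93 resulted (camera adjusted p = 4.16e-18, adjusted p = 0.366 with an estimated correlation), or 2.33 with 16 up without slide 16. Of the iron acquisition genes, 29 of 36 members rose and 7 did not pass (30 up and 1 down adjusted over the list alone). The median was 1.34 (camera adjusted p = 9.2e-18, adjusted p = 0.366 with an estimated correlation), or 1.60 with 30 up without slide 16. Members included entC at 2.90 ± 0.34 (adjusted p = 0.0039), fhuF at 2.73 ± 0.31 and entE at 2.64 ± 0.27. Without slide 16 they read 3.18, 3.57 and 2.69. The small RNA ryhB, made when iron is short, rose by 3.52 ± 0.34 (adjusted p = 0.00241), or 4.57 without slide 16. In the cysteine and sulphur list, 15 of 26 members rose, 2 fell and 9 did not pass (19 up and 3 down adjusted over the list alone). Its median was 1.40 (camera adjusted p = 1.56e-05, adjusted p = 0.574 with an estimated correlation), or 1.76 with 19 up and 2 down without slide 16. Members included the sulphate-binding protein sbp at 2.23 ± 0.31 (adjusted p = 0.00651), cysA of sulphate transport at 2.23 ± 0.26 and cysN of sulphate activation at 2.22 ± 0.44. Without slide 16 they read 2.58, 2.90 and 2.76. In the nitric oxide list, 5 of 9 members rose and 4 did not pass (5 adjusted over the list alone). A median of 0.74 resulted (camera adjusted p = 0.00645, adjusted p = 0.366 with an estimated correlation), or 0.82 with 5 up without slide 16. Members included hmp at 2.77 ± 0.089 (adjusted p = 0.000152), ygbA at 1.21 ± 0.096 and ytfE, which repairs Fe-S clusters, at 0.99 ± 0.14. Without slide 16 they read 4.23, 1.78 and 1.75. In the heat shock list, 4 of 20 members rose and 16 did not pass (8 adjusted over the list alone). The median was 0.77 (camera adjusted p = 3.05e-05, adjusted p = 0.7 with an estimated correlation), or 1.29 with 16 up without slide 16. Members included htpX at 2.07 ± 0.17 (adjusted p = 0.0014), or 2.98 without slide 16, and dnaK at 1.05 ± 0.23, or 1.68 without slide 16. In aromatic amino acid biosynthesis, 3 of 13 members rose and 10 did not pass (3 adjusted over the list alone). Its median was 0.14 (camera adjusted p = 0.0142, adjusted p = 0.574 with an estimated correlation), or 0.14 with 3 up without slide 16. In the phage shock list, 2 of 7 members rose and 5 did not pass (5 adjusted over the list alone). A median of 0.30 resulted (camera adjusted p = 0.00854, adjusted p = 0.511 with an estimated correlation), or 0.68 with 4 up without slide 16. In branched-chain amino acid biosynthesis, 1 of 13 members rose and 12 did not pass (none adjusted over the list alone). The median was 0.49 (camera adjusted p = 0.0279, adjusted p = 0.878 with an estimated correlation), or 0.34 with 2 up without slide 16 (camera adjusted p = 0.0823). The zinc-binding periplasmic protein zinT rose by 3.55 ± 0.52 (adjusted p = 0.00838), or 3.69 without slide 16, while cydA fell, at -1.42 ± 0.077 (adjusted p = 0.000485), or -1.79 without slide 16, and hemL rose 2.14-fold (adjusted p = 0.0207) with a log2 of 1.44 without slide 16.

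In anaerobic respiration, 27 of 39 members fell and 12 did not pass (29 adjusted over the list alone). Its median was -1.18 (camera adjusted p = 7.93e-18, adjusted p = 0.366 with an estimated correlation), or -1.72 with 29 down without slide 16. The nitrate reductase genes narG (b1224) and narH fell, at -2.22 ± 0.15 (adjusted p = 0.000795), or -3.20 without slide 16 and at -2.26 ± 0.12, or -3.37 without slide 16. Other members at the bottom were narK at -2.10 ± 0.29 and fdnG at -2.04 ± 0.14, or -3.34 and -3.04 without slide 16. Lysine decarboxylase cadA fell, at -2.89 ± 0.51 (adjusted p = 0.0156), or -3.92 without slide 16 and its transporter cadB at -2.34 ± 0.39, or -3.15 without slide 16. In purine biosynthesis, 9 of 15 members fell and 6 did not pass (13 adjusted over the list alone). A median of -1.04 resulted (camera adjusted p = 1.88e-08, adjusted p = 0.366 with an estimated correlation), or -1.87 with 15 down without slide 16. Members included purT at -1.37 ± 0.18 (adjusted p = 0.00579), or -2.34 without slide 16. In NADH dehydrogenase I, 11 of 13 members fell and 2 did not pass (13 adjusted over the list alone). The median was -0.78 (camera adjusted p = 2.31e-08, adjusted p = 0.462 with an estimated correlation), or -1.25 with 12 down without slide 16. Of the ribosomal protein genes, 28 of 52 members fell and 24 did not pass (36 adjusted over the list alone). Its median was -0.61 (camera adjusted p = 3.75e-17, adjusted p = 0.366 with an estimated correlation), or -0.99 with 40 down without slide 16. In the acid resistance list, 5 of 14 members fell and 9 did not pass (8 adjusted over the list alone). A median of -0.75 resulted (camera adjusted p = 1.58e-05, adjusted p = 0.462 with an estimated correlation), or -1.56 with 13 down without slide 16. Members included hdeD at -1.64 ± 0.17 (adjusted p = 0.00275), or -2.77 without slide 16. In glycolysis, 1 of 13 members rose, 6 fell and 6 did not pass (1 up and 7 down adjusted over the list alone). The median was -0.54 (camera adjusted p = 0.00037, adjusted p = 0.366 with an estimated correlation), or -1.03 with 1 up and 10 down without slide 16. Without slide 16, 4 more lists passed: fermentation and hydrogenases (median -0.48, camera adjusted p = 0.00283), ATP synthase (-0.66, camera adjusted p = 0.0118), Fe-S cluster assembly (0.58, camera adjusted p = 0.00552) and histidine biosynthesis (-0.65, camera adjusted p = 0.0202), and none held with an estimated correlation (adjusted p from 0.578 to 0.677). Fry did not call heat shock and branched-chain amino acids (adjusted p 0.0921 and 0.331). Without replicate 1 or 2 of this series 129 and 189 genes passed.

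The hemA cultures with iCORM-3 served as the compound control. Pyrimidine biosynthesis genes fell most: pyrB (b4245) and pyrI, the subunits of aspartate transcarbamoylase, at -5.84 ± 1.05 (adjusted p = 0.0116) and -5.80 ± 0.85, and carA at -5.50 ± 0.33 (adjusted p = 0.000637). The highest gene was again spy, at 5.07 ± 0.13 (adjusted p = 8.31e-05) or 33.6-fold, and members of the purine, sulphur and ribonucleotide reductase lists rose. Over all genes, 541 rose and 508 fell, 105 and 130 of them by at least 2-fold.

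In pyrimidine biosynthesis, 11 of 11 members fell (11 adjusted over the list alone). Its median was -4.13 (camera adjusted p = 6.04e-09, adjusted p = 0.366 with an estimated correlation). The salvage gene upp, uracil phosphoribosyltransferase, at -4.13 ± 0.23 (adjusted p = 0.000518) fell with them. In anaerobic respiration, 28 of 39 members fell and 11 did not pass (29 adjusted over the list alone). A median of -1.09 resulted (camera adjusted p = 3.39e-14, adjusted p = 0.366 with an estimated correlation). Members included fdnG at -3.27 ± 0.14 (adjusted p = 0.000347), narK at -2.61 and nirB at -1.84. Of the ribosomal protein genes, 36 of 52 members fell and 16 did not pass (40 adjusted over the list alone). The median was -0.87 (camera adjusted p = 1.19e-14, adjusted p = 0.366 with an estimated correlation). In NADH dehydrogenase I, 8 of 13 members fell and 5 did not pass (8 adjusted over the list alone). Its median was -0.60 (camera adjusted p = 0.00193, adjusted p = 0.606 with an estimated correlation). In ATP synthase, none of the 9 members passed limma's test over all genes or adjusted over the list alone. A median of -0.46 resulted (camera adjusted p = 0.0291, adjusted p = 0.795 with an estimated correlation). Lysine decarboxylase cadA fell, at -3.47 ± 0.51 (adjusted p = 0.00637).

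In purine biosynthesis, 9 of 15 members rose, 1 fell and 5 did not pass (10 up and 1 down adjusted over the list alone). The median was 1.08 (camera adjusted p = 0.000441, adjusted p = 0.511 with an estimated correlation). Members included purA at 1.72 ± 0.24 (adjusted p = 0.00584) and the xanthine transporter xanP at 2.77 ± 0.40 (adjusted p = 0.00595). In the cysteine and sulphur list, 16 of 26 members rose, 2 fell and 8 did not pass (19 up and 2 down adjusted over the list alone). Its median was 0.85 (camera adjusted p = 5.8e-05, adjusted p = 0.581 with an estimated correlation). Members included cysK, cysteine synthase A, at 2.71 ± 0.45 (adjusted p = 0.00936) and cysN at 2.08. In the Cpx and Bae list, 10 of 18 members rose and 8 did not pass (10 adjusted over the list alone). A median of 0.72 resulted (camera adjusted p = 5.35e-05, adjusted p = 0.438 with an estimated correlation). Members included mdtA at 1.81 ± 0.15 (adjusted p = 0.00129) and cpxP at 1.35 ± 0.21 (adjusted p = 0.007). Of the iron acquisition genes, 12 of 36 members rose and 24 did not pass (21 adjusted over the list alone). The median was 0.51 (camera adjusted p = 2.01e-05, adjusted p = 0.581 with an estimated correlation). Members included fhuF at 1.70 ± 0.31 (adjusted p = 0.0117) and fhuC at 1.25, and entF, not well above background at the start, rose at least 1.79-fold (adjusted p = 0.0239). In the ribonucleotide reductases, 5 of 9 members rose and 4 did not pass (6 adjusted over the list alone). Its median was 1.03 (camera adjusted p = 0.00204, adjusted p = 0.57 with an estimated correlation). Members included nrdI at 2.86 ± 0.32 (adjusted p = 0.00319) and nrdH at 2.39. In the nitric oxide list, 5 of 9 members rose and 4 did not pass (5 adjusted over the list alone). A median of 0.60 resulted (camera adjusted p = 0.00175, adjusted p = 0.366 with an estimated correlation). Members included hmp at 1.95 ± 0.089 (adjusted p = 0.000347) and ygbA at 1.05. In Fe-S cluster assembly, 5 of 16 members rose and 11 did not pass (8 adjusted over the list alone). The median was 0.62 (camera adjusted p = 0.00275, adjusted p = 0.606 with an estimated correlation). Highest was sufA at 1.69 ± 0.12 (adjusted p = 0.00102). In the RpoS list, 8 of 18 members rose and 10 did not pass (9 adjusted over the list alone). Its median was 0.54 (camera adjusted p = 0.000382, adjusted p = 0.366 with an estimated correlation). Members included dps, a DNA-binding ferritin, at 1.62 ± 0.16 (adjusted p = 0.00232). The oxidase gene cydA read 0.29 ± 0.077 (adjusted p = 0.0397) and turned to -0.038 under median centring. Fry did not call ATP synthase (adjusted p = 0.219). Without replicate 1 or 2 of this series, 272 and 144 genes passed.

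The CORM-3 responses of hemA and WT, each against its own start, were compared. Starts differed too: in single channels, not tested, cadA read 11.34 in hemA and 7.84 in WT, opposite to its difference, and hmp 7.93 and 7.35, not opposite. Responses of sulphur assimilation genes were higher in hemA: cysJ (b2764), of sulphite reductase, differed by 4.36 ± 0.67 (adjusted p = 0.0236), or 4.72 without slide 16, cysD by 3.75 ± 0.64, or 4.39 without slide 16, and cysN by 3.56 ± 0.62, or 4.10 without slide 16. The hmp response was higher in hemA by 2.79 ± 0.13 (adjusted p = 0.0023), or 4.24 without slide 16, the largest outside the cys genes. Lower in hemA were the responses of cadA, at -3.54 ± 0.72 (adjusted p = 0.0449), or -4.57 without slide 16, of ibpB, at -3.48 ± 0.59 (adjusted p = 0.029), or -2.67 without slide 16 (adjusted p = 0.0607), and of spy, at -2.43 ± 0.18 (adjusted p = 0.00822), or -0.54 without slide 16 (adjusted p = 0.254). In all 147 genes were higher and 120 lower in hemA, against 98 and 96 without slide 16, with 139 called in both, and 399 with the sign of the doubtful arrays turned.

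In the cysteine and sulphur list, 13 of 26 members were higher and 13 did not pass (16 higher and 1 lower adjusted over the list alone). A median of 1.96 resulted (camera adjusted p = 1.15e-08, adjusted p = 0.511 with an estimated correlation), or 2.29 with 11 higher without slide 16. In anaerobic respiration, 20 of 39 members were lower and 19 did not pass (3 higher and 24 lower adjusted over the list alone). The median was -1.05 (camera adjusted p = 2.43e-09, adjusted p = 0.438 with an estimated correlation), or -1.52 with 22 lower without slide 16. Members included narG at -2.28 ± 0.21 (adjusted p = 0.00943), or -3.27 without slide 16, narH at -2.17 ± 0.18, or -3.28 without slide 16, and nirB at -1.94 ± 0.33 (adjusted p = 0.0287), or -3.27 without slide 16, and the same list stood 1.40 higher in hemA before addition. Of the ribosomal protein genes, 25 of 52 members were higher and 27 did not pass (36 adjusted over the list alone). Its median was 0.84 (camera adjusted p = 1.23e-20, adjusted p = 0.366 with an estimated correlation), or 0.32 with 4 higher without slide 16. In the nitric oxide list, 3 of 9 members were higher and 6 did not pass (5 adjusted over the list alone). A median of 0.57 resulted (camera adjusted p = 0.0128, adjusted p = 0.366 with an estimated correlation), or 0.64 with 3 higher without slide 16. Members included ygbA and ytfE, not well above background in WT at the start and given no size. Of the iron acquisition genes, 5 of 36 members were higher and 31 did not pass (11 adjusted over the list alone). The median was 0.46 (camera adjusted p = 2.42e-05, adjusted p = 0.581 with an estimated correlation), or 0.60 with 7 higher without slide 16. Members included fecR at 0.81 ± 0.16 (adjusted p = 0.0408), or 1.01 without slide 16, and fepG and fepD, also dim in WT at the start and given no size. In the RpoS list, 4 of 18 members were lower and 14 did not pass (6 adjusted over the list alone). Its median was -0.62 (camera adjusted p = 0.000128, adjusted p = 0.366 with an estimated correlation), or -0.58 with 4 lower without slide 16. In the ribonucleotide reductases, 2 of 9 members were higher and 7 did not pass (4 adjusted over the list alone). A median of 1.02 resulted (camera adjusted p = 0.00448, adjusted p = 0.581 with an estimated correlation), or 1.04 with 3 higher without slide 16. Members included nrdE, also dim in WT at the start and given no size. In haem biosynthesis, 2 of 13 members were higher and 11 did not pass (3 adjusted over the list alone). The median was 0.42 (camera adjusted p = 0.00193, adjusted p = 0.511 with an estimated correlation), or 0.37 with 1 higher without slide 16. In the heat shock list, 3 of 20 members were lower and 17 did not pass (4 adjusted over the list alone). Its median was -0.68 (camera adjusted p = 0.000451, adjusted p = 0.791 with an estimated correlation), or -0.25 with none past the test without slide 16 (camera adjusted p = 0.399). In the phage shock list, 2 of 7 members were lower and 5 did not pass (3 adjusted over the list alone). A median of -0.35 resulted (camera adjusted p = 0.0155, adjusted p = 0.511 with an estimated correlation), or -0.038 with none past the test without slide 16 (camera adjusted p = 0.288). In ATP synthase, 1 of 9 members was higher and 8 did not pass (6 adjusted over the list alone). The median was 1.00 (camera adjusted p = 0.000268, adjusted p = 0.581 with an estimated correlation), or 0.40 with none past the test without slide 16 (camera adjusted p = 0.0823). In the fermentation list, 6 of 28 members were higher, 2 were lower and 20 did not pass (12 higher and 7 lower adjusted over the list alone). Its median was 0.49 (camera adjusted p = 0.0375, adjusted p = 0.908 with an estimated correlation), or 0.21 with 2 higher and 7 lower without slide 16 (camera adjusted p = 0.741). Its member ldhA was lower at -2.34 ± 0.35 (adjusted p = 0.0225), or -1.99 without slide 16. In histidine biosynthesis, none of the 8 members passed limma's test over all genes or adjusted over the list alone. A median of -0.52 resulted (camera adjusted p = 0.0306, adjusted p = 0.795 with an estimated correlation), or -0.90 with none past the test without slide 16. In branched-chain amino acid biosynthesis, none of the 13 members passed limma's test over all genes or adjusted over the list alone. The median was 0.40 (camera adjusted p = 0.0329, adjusted p = 0.878 with an estimated correlation), or 0.36 with 1 higher without slide 16. Without slide 16, lists gained were NADH dehydrogenase I (-0.66, camera adjusted p = 0.000905), Fe-S cluster assembly (0.92, camera adjusted p = 0.00213), purine biosynthesis (-0.88, camera adjusted p = 2.74e-05), glycolysis (-0.40, camera adjusted p = 0.000809) and acid resistance (-0.81, camera adjusted p = 0.00133). Of these, none held with an estimated correlation (adjusted p from 0.265 to 0.52). Fry did not call fermentation, ATP synthase, iron, heat shock, histidine, branched-chain amino acids and ribonucleotide reductases (adjusted p from 0.0827 to 0.442).

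Other responses lower in hemA were those of glnH, the glutamine-binding protein, at -2.84 ± 0.28 (adjusted p = 0.0101), or -3.43 without slide 16, and bssS at -3.29 ± 0.53 (adjusted p = 0.0257), or -2.45 without slide 16 (adjusted p = 0.0533). The cydA response did not differ past the test, at -0.16 (95% interval -0.43 to 0.11), or -0.53 (-0.83 to -0.22) without slide 16, nor did that of norV, at 0.028 (-0.27 to 0.33), or 0.089 (-0.23 to 0.40). Slide 15 held 3 arrays of each strain at matched times, from 1 culture each, in opposite dyes and also part of the pooled difference. Within that slide cysJ differed by 4.04, hmp by 3.34, cadA at -5.32, glnH at -4.11, ibpB at -2.03, spy at -1.60, ldhA at -1.73 and bssS at -2.19. The list medians there were 1.60 for cysteine and sulphur, -1.27 for anaerobic respiration, 0.72 for ribosomal proteins, 0.90 for nitric oxide, 0.59 for iron acquisition, -0.12 for heat shock, -0.31 for phage shock, 1.17 for ATP synthase and 0.29 for fermentation. With a replicate of hemA with CORM-3 left out, which leaves 1 culture, few or no genes passed (counts below). Median centring left 80.8% of the calls higher against 55.1%.

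The difference between CORM-3 and iCORM-3 in hemA compared the carbonyl compound with its inactive form at the same dose and times. Responses of envelope stress genes were higher with CORM-3: spy differed by 2.21 ± 0.18 (adjusted p = 0.00865), yebE by 2.68 ± 0.19 and cpxP by 2.16 ± 0.29. Without slide 16 they differed by 4.10, 3.62 and 3.28. The pyrimidine gene carA (b0032) was higher by 5.90 ± 0.47 (adjusted p = 0.00865), or 5.83 without slide 16, and the purine gene purT (b1849) lower at -3.01 ± 0.26 (adjusted p = 0.00865), or -3.97 without slide 16. The oxidase gene cydA was lower with CORM-3 at -1.71 ± 0.11 (adjusted p = 0.00865), or -2.08 without slide 16. In all 109 genes were higher and 76 lower with CORM-3, against 155 and 176 without slide 16, with 151 called in both, and 540 with the sign of the doubtful arrays turned.

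In the Cpx and Bae list, 10 of 18 members were higher and 8 did not pass (15 adjusted over the list alone). Its median was 1.41 (camera adjusted p = 5.99e-14, adjusted p = 0.366 with an estimated correlation), or 1.56 with 11 higher without slide 16. Members included mdtA at 2.41 ± 0.21 (adjusted p = 0.00865), or 3.37 without slide 16. Of the iron acquisition genes, 5 of 36 members were higher and 31 did not pass (16 adjusted over the list alone). A median of 0.85 resulted (camera adjusted p = 1.52e-09, adjusted p = 0.511 with an estimated correlation), or 1.09 with 11 higher without slide 16. Members included fecR at 0.92 ± 0.16 (adjusted p = 0.0334), or 1.12 without slide 16. In pyrimidine biosynthesis, 5 of 11 members were higher and 6 did not pass (11 adjusted over the list alone). The median was 3.41 (camera adjusted p = 3.72e-10, adjusted p = 0.366 with an estimated correlation), or 3.08 with 5 higher without slide 16. Members included carB at 5.22 ± 0.45 and upp at 3.66 ± 0.32, or 4.94 and 3.08 without slide 16. In purine biosynthesis, 10 of 15 members were lower and 5 did not pass (13 adjusted over the list alone). Its median was -2.10 (camera adjusted p = 2.45e-13, adjusted p = 0.366 with an estimated correlation), or -2.78 with 13 lower without slide 16. Members included purA at -2.84 ± 0.34 (adjusted p = 0.0146), or -3.50 without slide 16, and xanP was lower at -4.19 ± 0.56 (adjusted p = 0.0198), or -5.21 without slide 16. In the terminal oxidases, 3 of 11 members were lower and 8 did not pass (1 higher and 3 lower adjusted over the list alone). A median of -0.11 resulted (camera adjusted p = 0.028, adjusted p = 0.511 with an estimated correlation), or -0.068 with 3 lower without slide 16. Past the test were the bd-I genes, with cydB at -1.68 ± 0.15 and cydX at -1.47 ± 0.21, or -1.66 and -1.54 without slide 16. Unequal starts may count here: they differed by 1.30 for cydB, 0.65 for cydA and 0.33 for cydX, not tested. After addition cydB differed by -0.36, cydA by -1.42 and cydX by -1.21. In the acid resistance list, 4 of 14 members were lower and 10 did not pass (1 higher and 8 lower adjusted over the list alone). The median was -1.11 (camera adjusted p = 0.000441, adjusted p = 0.511 with an estimated correlation), or -1.98 with 9 lower without slide 16. Members included hdeD at -2.05 ± 0.24 (adjusted p = 0.0133), or -3.18 without slide 16. In the RpoS list, 2 of 18 members were lower and 16 did not pass (10 adjusted over the list alone). Its median was -0.53 (camera adjusted p = 3.6e-06, adjusted p = 0.366 with an estimated correlation), or -0.55 with 3 lower without slide 16. In the phage shock list, 2 of 7 members were higher and 5 did not pass (2 adjusted over the list alone). A median of 0.30 resulted (camera adjusted p = 0.00301, adjusted p = 0.503 with an estimated correlation), or 0.72 with 3 higher without slide 16. In the SoxRS list, 1 of 20 members was higher and 19 did not pass (1 adjusted over the list alone). The median was 0.38 (camera adjusted p = 0.0307, adjusted p = 0.581 with an estimated correlation), or 0.32 with 2 higher without slide 16. In NADH dehydrogenase I, none of the 13 members passed limma's test over all genes or adjusted over the list alone. Its median was -0.27 (camera adjusted p = 0.0155, adjusted p = 0.777 with an estimated correlation), or -0.72 with 4 lower without slide 16. In Fe-S cluster assembly, none of the 16 members passed limma's test over all genes or adjusted over the list alone. A median of -0.42 resulted (camera adjusted p = 0.0153, adjusted p = 0.749 with an estimated correlation), or -0.052 with none past the test without slide 16 (camera adjusted p = 0.889). Without slide 16, lists gained were anaerobic respiration (-0.38, camera adjusted p = 3.79e-05), fermentation (-0.60, camera adjusted p = 0.000677), heat shock (0.84, camera adjusted p = 1.32e-05), aromatic amino acids (0.22, camera adjusted p = 0.0303), ribosomal proteins (-0.42, camera adjusted p = 9.32e-06) and glycolysis (-0.85, camera adjusted p = 3.74e-05). Of these, none held with an estimated correlation (adjusted p from 0.265 to 0.636). Fry did not call NADH dehydrogenase I, SoxRS and Fe-S (adjusted p from 0.105 to 0.264). The sets already differed before addition, opposite in sign to the response difference, by a median of -3.79 for pyrimidine, 2.1 for purine, 0.67 for NADH dehydrogenase, 0.40 for RpoS, -0.38 for iron, 0.35 for Fe-S, 0.21 for oxidase and -0.259 for Cpx and Bae genes.

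The hmp response was higher with CORM-3 by 0.82 ± 0.13 (adjusted p = 0.0273), or 2.27 without slide 16. Responses that did not differ past the test were those of hemL, at 0.11 (95% interval -0.62 to 0.85), or 0.45 (-0.29 to 1.18) without slide 16, and of cysK, at -0.74 (-2.31 to 0.83), or -0.37 (-1.92 to 1.18). The norV responses differed by -0.12 (-0.42 to 0.18), or -0.059 (-0.37 to 0.26), also not past the test. For nirB the difference was -0.080 (-0.89 to 0.73) over all arrays and -1.40 (-2.02 to -0.79, adjusted p = 0.0284) without slide 16. The sets of hemA cultures shared no slide and no scan day, so no value within a slide can be given, and batch and compound cannot be told apart. With 1 replicate of either set left out, few or no genes passed (counts below).

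**Figure D2:**
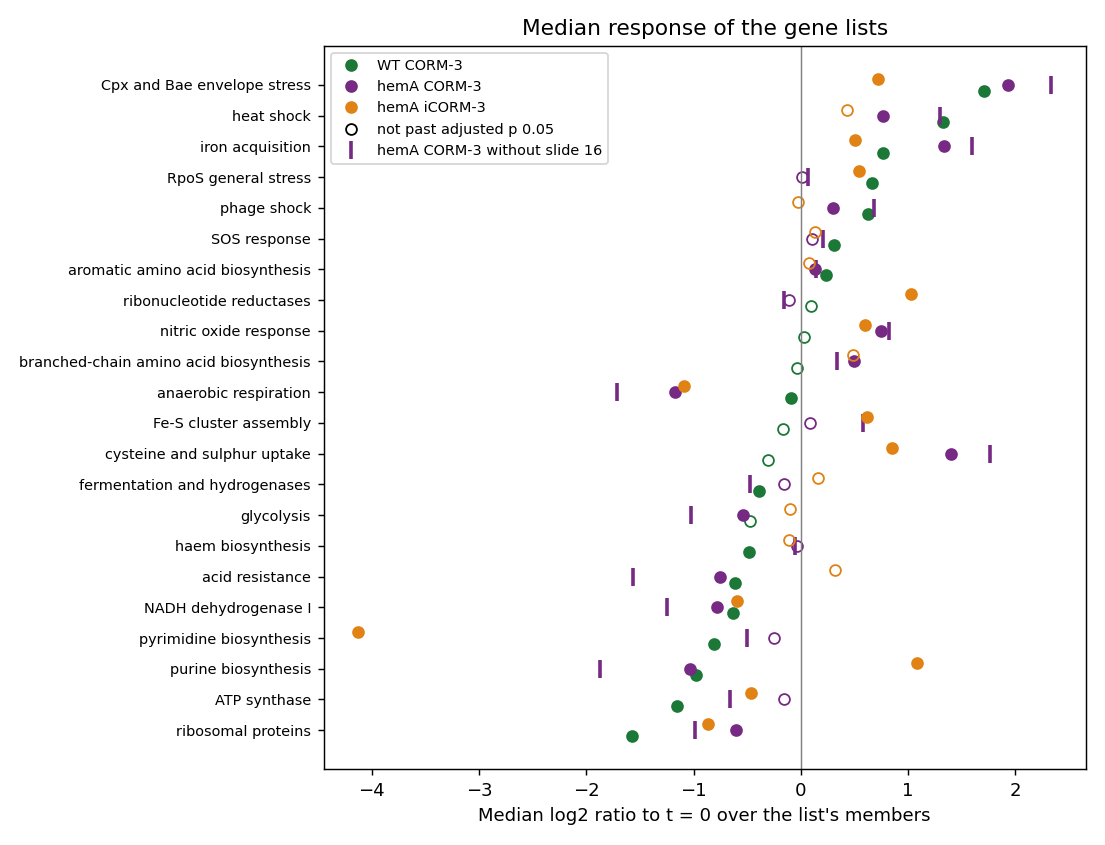
Median log2 response (horizontal axis) of the members of 22 gene lists (vertical axis) in the 3 time courses, with filled points where the list passed camera's adjusted p of 0.05 and ticks for hemA with CORM-3 without slide 16. The Cpx and Bae list lies at 1.70 in WT, 1.93 in hemA with CORM-3 and 0.72 in hemA with iCORM-3.

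Fitted at single times, the number of genes past the test in WT was 55 at 10 min, 549 at 20, 863 at 40, 1357 at 60 and 1088 at 120 min, and with iCORM-3 it was 77, 667, 287, 1191 and 1161. In hemA with CORM-3 it was 231, 580, 553 and 635 up to 60 min, and at 120 min limma called 0 genes, with 1 at an unadjusted p under 0.05, where slide 16 arrays of opposite sign met the others. Without slide 16, which leaves 1 culture at 10 min, it was 76, 286, 1002, 1391 and 1474 at the 5 times. Between the strains 100, 7, 256 and 462 genes differed from 20 min on, and at 10 min limma called 0, with 379 at an unadjusted p under 0.05. Without slide 16 these were 4, 16, 224, 198 and 302 from 10 min on, so the order of the times changed. Between the compounds 70, 314, 81, 356 and 564 genes differed at the 5 times, against 40, 82, 144, 227 and 330 without slide 16.

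The spy response in WT was 8.34 at 10 min and 9.62 at 120 min (adjusted p = 3.25e-06), and with iCORM-3 it was 5.21 and 3.46. With iCORM-3, hmp stood at 0.12 at 10 min, 2.02 at 40 min and 4.10 at 60 min (adjusted p = 0.000136), and with CORM-3 in hemA it was already 2.16 at 10 min and reached 5.98 at 120 min without slide 16. In WT, hmp stayed between -0.074 and 0.061 at the 5 times. With iCORM-3, cadA was -0.28 at 10 min and -6.14 at 120 min (adjusted p = 0.000472), xanP 3.51 and 0.72, and entC 3.19 at 20 min and 0.00085 at 120 min.

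**Figure D3:**
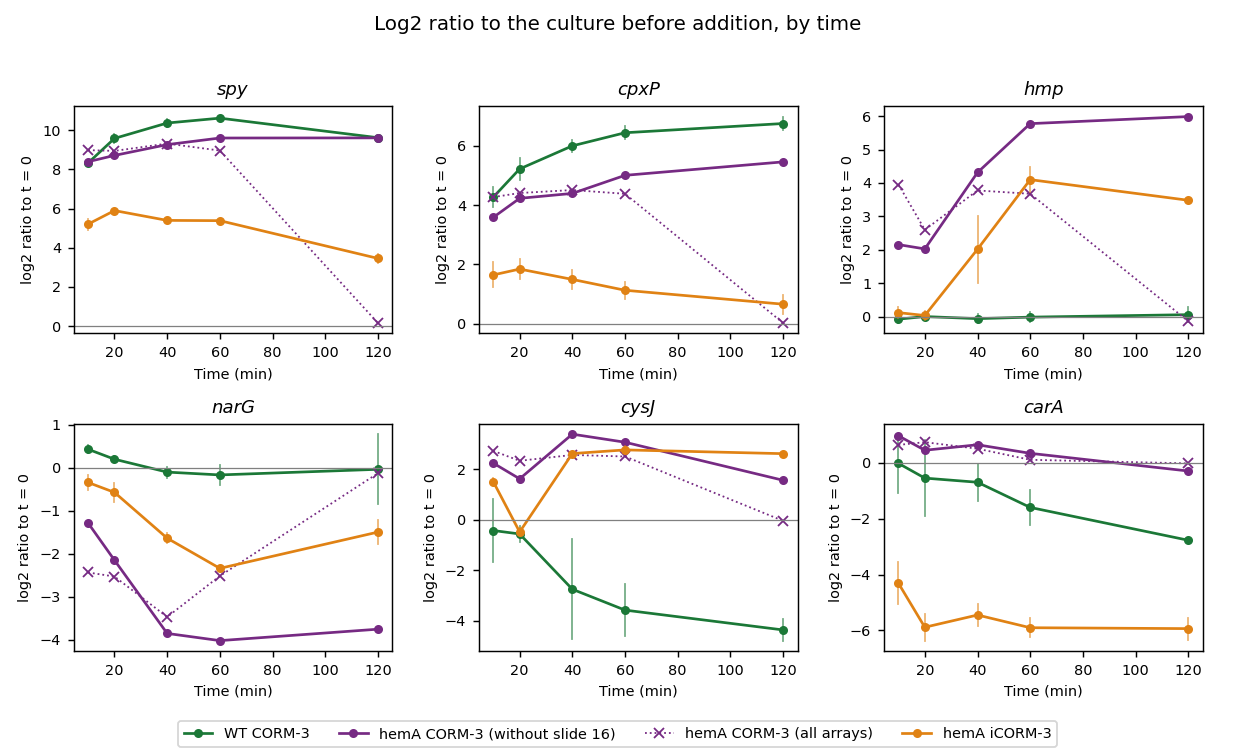
Log2 ratio to the start (vertical axes) of spy, cpxP, hmp, narG, cysJ and carA against minutes after addition (horizontal axes) for WT with CORM-3, hemA with CORM-3 over all arrays and without slide 16, and hemA with iCORM-3, with points for means and bars between the 2 experiments. At 120 min spy stands at 9.61 in hemA with CORM-3 without slide 16, and carA at -5.94 with iCORM-3.

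Across genes, which are not independent replicates, the mean response of hemA to CORM-3 correlated with that of WT at r = 0.64 (0.58 to 0.63 over pairings of single cultures), or 0.68 without slide 16. Both strains shared 200 genes that rose, against 51.2 for independent lists, and 157 that fell, against 43.4, with 17 of opposite sign, or 291 against 78 and 255 against 73.5 without slide 16. With iCORM-3 the correlation was 0.55 (0.51 to 0.55), or 0.58 without slide 16, and 164 genes rose and 175 fell in both, against 42.8 and 39.5, with 27 of opposite sign, or 231 against 64.1 and 264 against 70.7 without slide 16. Of the 35 lists, 6 passed in no comparison: TCA cycle, OxyR regulon, glutathione and thioredoxin, methionine biosynthesis, flagella and chemotaxis, and multidrug efflux, with lowest camera adjusted p of 0.286, 0.136, 0.212, 0.495, 0.3 and 0.132. Of the 83 list calls, 0 held with a correlation between genes estimated from these 8 values, where the lowest adjusted p was 0.366. A list's median, mean and test differed in sign in 0 of them.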

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

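Tests on slide 16 arrays, on starting levels and on a return to the WT level were chosen after the result was seen, as were values without slide 16.

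The arrays of slide 16 stood apart from their dye-swap partners. A failed hybridisation is argued against, since each of its 8 arrays reached an absolute correlation of at least 0.859 with an array off the slide. Of the 8 arrays, 7 correlated better, by over 0.1, with an array of another time than with any of their own, against 1 of the 12 others of the series, but 2 of the 7 are 120 min arrays of opposite sign, with -0.36 and -0.39 at best with another time. The other 5 are in line with time labels out of place, and for those 2 a turned sign alone would give the gap. Which label each array should carry stays open, no array was reassigned, and no biological explanation was tested, since dye swaps share their RNA.

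Of 39 anaerobic respiration genes, 20 responded lower to CORM-3 in hemA than in WT and 19 did not pass. The list's median difference was -1.05 (adjusted p = 0.438 with an estimated correlation), or -1.52 without slide 16. The offset and dimmer WT arrays are argued against as the whole cause, since processed intensities, which carry no offset, gave -0.857. WT levels too near background to fall stay open, as the 20 members well above background in WT gave -0.778, between the bounds set beforehand, though the -1.01 without slide 16 lies past the bound against it. A higher start in hemA that returned towards the WT level may account for part of the difference. The list stood 1.40 higher before addition and both differences summed to 0.3, or -0.031 without slide 16. These values are coupled where arrays share the RNA of the start. Over the members well above background the start was only 0.43 higher and the sum -0.13, or -0.48 without slide 16. A strain effect on the response itself stays open and untested.

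Over all genes, 5 of 11 pyrimidine genes were higher and 10 of 15 purine genes lower with CORM-3 than with iCORM-3 (adjusted p = 0.366 with an estimated correlation for each list). Unequal starting levels are a candidate explanation: before addition the CORM-3 set differed from the iCORM-3 set by a median of -3.79 for pyrimidine and 2.1 for purine genes, and after it at -0.29 and -0.77. The same explanation is argued against for the Cpx and Bae list, whose start differed by -0.259 against a response difference of 1.41. The slides and scan days cannot be told apart from the compound, since the sets share neither, and the pyrimidine median with the scan day as a random block was 3.31. An effect of carbon monoxide stays open and untested.

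Results that differed between groups by a test of the difference itself follow as values, the CORM-3 response of hemA minus that of WT first. Over the mean of the times 267 genes differed, and at 20, 40, 60 and 120 min 100, 7, 256 and 462, or 16, 224, 198 and 302 without slide 16. Higher in hemA were cysJ by 4.36, cysD by 3.75, cysN by 3.56, cysI by 3.23, cysH by 3.03, hmp by 2.79, cysC by 2.66 and cysA by 2.55. Lower in hemA were cadA at -3.54, ibpB at -3.48, bssS at -3.29, glnH at -2.84, cadB at -2.64, b3914 at -2.47, spy at -2.43 and ldhA at -2.34. Lists follow with the single-channel start of the CORM-3 hemA set against WT in brackets, not tested. Medians higher in hemA were haem at 0.42 (-0.068), fermentation at 0.49 (-0.57), ATP synthase at 1.00 (-0.91), iron at 0.46 (-0.19) and nitric oxide at 0.57 (0.24). Others were cysteine and sulphur at 1.96 (-0.83), branched-chain amino acids at 0.40 (-0.53), ribosomal proteins at 0.84 (0.14) and ribonucleotide reductases at 1.02 (0.74). Lower medians were anaerobic respiration at -1.05 (1.55), phage shock at -0.35 (0.48), heat shock at -0.68 (-0.009), histidine at -0.52 (0.34) and RpoS at -0.62 (0.68). Where signs are opposite, as also for the genes cysJ, cysD, cysN and cadA, unequal starts are a candidate explanation. Calls for heat shock, phage shock, ATP synthase and fermentation ended without slide 16, as did those for ibpB, bssS, b3914 and spy, while the medians of ribosomal proteins and histidine biosynthesis went to 0.32 and -0.90 and hmp to 4.24.

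For hemA, CORM-3 minus iCORM-3, 185 genes differed over the mean of the times, and at 10, 20, 40, 60 and 120 min 70, 314, 81, 356 and 564, or 40, 82, 144, 227 and 330 without slide 16. Higher with CORM-3 were carA by 5.90, carB by 5.22, upp by 3.66, uraA by 3.32, codB by 3.25, ykgM by 2.87, yebE by 2.68 and yncE by 2.57, where the start of ykgM with iCORM-3 was not well above background, so its size is not reliable. Lower with CORM-3 were xanP at -4.19, purT at -3.01, purA at -2.84, purE at -2.60, lysC at -2.59, purM at -2.58, purD at -2.47 and purC at -2.31. Lists with a higher median were SoxRS at 0.38, iron at 0.85, Cpx and Bae at 1.41, phage shock at 0.30 and pyrimidine at 3.41. Those with a lower median were terminal oxidases at -0.11, NADH dehydrogenase I at -0.27, Fe-S at -0.42, purine at -2.10, acid resistance at -1.11 and RpoS at -0.53. The call for Fe-S cluster assembly ended without slide 16, and the medians of terminal oxidases, NADH dehydrogenase I, phage shock and acid resistance went to -0.068, -0.72, 0.72 and -1.98. With an estimated correlation, 0 of these list differences held, with adjusted p between 0.366 and 0.908 for the strains and between 0.366 and 0.777 for the compounds.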

How the results depend on the processing

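Fits without slide 16, with the sign turned on 2 of its arrays, without 120 min and with the scan day as a random block were chosen after seeing the data, and all others before. Counts of genes past the test are given for the arrays before addition (main count 1113), WT with CORM-3 (1204), hemA with CORM-3 (640), hemA with iCORM-3 (1049), the strain difference (267) and the compound difference (185), with 9294 calls over single times, 83 list calls, and r of hemA with CORM-3 against WT (0.64) and against iCORM-3 (0.55). No background correction, no filter on dim probes, the median of probes and an intensity trend with robust variances left each of these within 1.5 times its main value, with lists not tested under the trend. With Agilent processed signals the strain difference held 533 genes and the compound difference 98, and with the authors' value table WT held 1820, the strain difference 534 and the compound difference 101. Median centring gave 115 for the compound difference and r 0.62 with WT, and cydA with iCORM-3 reversed to -0.038 from 0.29. Scaling after loess gave 168 for the strain difference and r 0.51 with iCORM-3. The causes of these were not tested.

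Fewer genes were tested over probes above background on all arrays, with counts of 235, 468, 185, 276, 104 and 58 in the order above, with 3148 calls at single times, 43 list calls and r 0.70 with WT. Fewer arrays stand behind the counts with the test RNA in Cy5 only, 461, 594, 97, 232, 0 (635 at an unadjusted p under 0.05 in limma) and 5, with 4092 at single times, and in Cy3 only, 616, 450, 94, 494, 1 and 25, with 5211. A log2 threshold of 1 gave 219, 359, 204, 235, 141 and 101, with 4368 at single times. Without slide 16, hemA with CORM-3 held 1264, the compound difference 331, and r was 0.68 with WT and 0.58 with iCORM-3. Turning the sign gave 1401 and 540, with r 0.67 with WT. Without 120 min, hemA with CORM-3 held 1057 and the compound difference 396, and gadA in WT reversed to 0.035 from -0.60, the cause of which was not tested. With an estimated correlation camera called 0 lists, and 0 without slide 16, and fry in place of camera called 76, with 63 of the 83.

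Fits to all arrays count each time as a value of its own, which narrows the errors. The fit without a block called 2503 for WT, 1732 for hemA with CORM-3, 2444 for iCORM-3, 1602 for the strain and 1494 for the compound difference. With a dye term for each slide these were 2563, 1345, 2367, 1499 and 1507, with r 0.62 and 0.50, with the slide as a random block 2111, 1317, 2021, 1337 and 1002, with 15309 at single times, and with the scan day as a random block 715 before addition, then 1198, 1580, 1134 and 753 for the last 4, with r 0.61 with WT. The replicate numbers share only a number: same-numbered deviations correlated at 0.20 for the strain and -0.073 for the compound difference. Between the arrays before addition and the CORM-3 series they were 0.55 for WT and -0.18 for hemA, signs that shared RNA of the start would give. The value for hemA with iCORM-3 was -0.22, so the negative sign is not particular to the CORM-3 set. The hemA channel of the arrays before addition correlated at 0.988 with the start of hemA with CORM-3 and at 0.951 with that of iCORM-3. Whether that RNA was shared stays open. With the replicate number as a fixed block the counts were 1074, 1190, 588, 983, 223 and 160, and with the culture as a random replicate block 2006 for WT, 1186, 1921, 970 and 869 for the others after addition.

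Leaving out a replicate leaves a group with 1 culture, assumed to vary like the others. The ranges were 770 to 1133 before addition, 472 (without WT replicate 1) to 1476 for WT, 129 (without its replicate 1, 189 without replicate 2, 418 without either iCORM-3 replicate) to 817 for hemA with CORM-3, and 144 (without its replicate 2, 272 without replicate 1) to 1411 for iCORM-3. For the strain difference they were 0 (without hemA CORM-3 replicate 2, 618 at an unadjusted p under 0.05, 15 without replicate 1, 91 without either iCORM-3 replicate, 127 and 106 without WT replicates 1 and 2) to 427 (without either replicate before addition). For the compound difference limma called 0 without hemA CORM-3 replicate 1 or iCORM-3 replicate 1 or 2 (540, 638 and 503 at an unadjusted p under 0.05), 22 without hemA CORM-3 replicate 2, and up to 327 without either replicate before addition. Calls at single times ran from 4514 to 9324, with 4741 and 4514 without iCORM-3 replicates 1 and 2, list calls from 81 to 92, r with WT from 0.60 (without WT replicate 1) to 0.64 and with iCORM-3 from 0.52 to 0.55.

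Of 447 gene values named by the rule, 444 kept direction and side of the threshold with no background correction, 412 with processed signals, 402 with median centring, 397 with scaling, 413 with the value table, 435 with no filter, 447 with the median of probes, 432 with the trend, 426 with the fixed replicate block, 419 without slide 16, 427 with the sign turned and 412 without 120 min. With Cy5 only it was 272, with the culture as a random replicate block 408, with all times and no block 397, and over the replicates left out 323 to 425. Of 439 values, 253 were kept with Cy3 only, 366 with the dye term, 383 with the slide block and 377 with the scan-day block, and 154 of 157 over probes above background on all arrays. The value of cydA and that of gadA were the only ones among them to change direction in the 28 settings run. Signal over background limits WT most, where down to 32.1% of probes were well above background.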

Other observations

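Medians of gene lists at single times, for which no list test was run, moved at different paces in WT with CORM-3. The Cpx and Bae list stood at 1.80 at 10 min, 2.37 at 40 min and 0.77 at 120 min. Heat shock genes read 1.23, 1.52 and 1.69 at those times, and phage shock genes 0.047, 0.44 and 1.66. Ribosomal protein genes went from -0.40 at 10 min to -2.30 at 120 min, ATP synthase genes from -0.085 to -2.66, and acid resistance genes from 0.53 to -2.18.

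In hemA with iCORM-3, the iron acquisition median was 1.47 at 20 min and -0.064 at 120 min, whereas in hemA with CORM-3 without slide 16 it was 1.92 and 0.68. The cysteine and sulphur median at 10, 20 and 40 min was 0.50, -0.21 and 1.54 with iCORM-3, and 1.58 (1 culture), 1.08 and 2.52 with CORM-3 without slide 16.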
